A study of Caenorhabditis elegans with 6 samples.

How the data were processed

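RNA was measured in whole wild-type Bristol N2 hermaphrodites of Caenorhabditis elegans that were 3 days old. The worms were fed the Escherichia coli strain OP50, the standard laboratory food and here the control, or 1 of the Lactococcus lactis strains L1 and L2. Each of the 3 groups had 2 libraries, 6 in all. The labels conflict on how long the worms were fed: the treatment protocol gives 6 hours and the series design gives 1 day. Nothing in the labels says that the libraries of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Camera with a preset correlation, the hypergeometric test and shuffles of genes, all described below, compare genes with other genes. Their p-values do not measure the spread between samples.

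Per the labels' protocols, about 200 worms per group were kept in RNAlater, total RNA was isolated with a lipid tissue kit, and polyadenylated RNA was selected with magnetic beads. Libraries were made with a SMARTer stranded kit, and the series design names Illumina HiSeq sequencing. The submitters' processing notes name Trim Galore 0.6.6, Trimmomatic 0.39, cutadapt 3.1, STAR 2.7.9a and featureCounts 2.0.1, and the builds ce11 and WBcel235. The role and order of these tools, their parameters, the annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart.

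The deposited files hold raw read counts per gene, 1 column per library and 46904 genes each, as whole numbers with no normalization, per the file headers and values. Totals were 21691687 and 17280251 counts for OP50 replicates 1 and 2. They were 29093902 and 24504954 for L1, and 24486716 and 29336753 for L2. The Ensembl gene annotation of WBcel235 held 46817 of the 46904 gene identifiers and lacked 87. Coordinates are those of that annotation, counted from 1. Gene names are those of the deposited files.

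Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed by filterByExpr with the groups given, a minimum count of 10 and a minimum total of 15, which left 15600 genes. Of these, 14933 were protein-coding and 473 were pseudogenes. Libraries were scaled by TMM. All 6 libraries entered 1 quasi-likelihood fit with a mean per group, so that the groups shared 1 estimate of the spread. The L1 vs OP50, L2 vs OP50 and L2 vs L1 contrasts and the mean of both L. lactis groups against OP50 were tested with the robust quasi-likelihood F-test. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of F and are approximate. Expression levels are CPM (counts scaled to a common library size) computed here from the deposited counts, with TMM-scaled library sizes, and are given as mean ± SD.

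The common biological coefficient of variation was 16.5%, with 3 residual and a median of 5.32 prior degrees of freedom. Replicates of a group correlated at 0.980 for OP50, 0.986 for L1 and 0.989 for L2 on the log CPM scale across genes, which are not independent replicates. Their counts differed by far more than sampling noise, with a chi-square per degree of freedom of 44.8, 38.0 and 17.1, so no pair was a library counted again. The test was checked on simulated counts drawn from the means and library sizes of these samples, with 200 genes changed by known folds. For L1 vs OP50, 5.97%, 40.9% and 76.2% of the genes changed by 1.5-, 2- and 4-fold were called among 15334 genes, and 14 of all 93 calls were of unchanged genes. For L2 vs OP50, the shares were 10.6%, 43.3% and 87.5% among 15342 genes, with 16 of 108 calls of unchanged genes. For L2 vs L1 they were 4.55%, 40.3% and 87.5% among 15342 genes, with 16 of 102. In each comparison the share of unchanged genes among the calls was above the rate that the adjusted p threshold is meant to hold. The test thus made too many false calls in these simulations.

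A set of 46 gene lists was fixed before the data were examined, as were the design, the alternatives and the rule for the genes named. Lists cover immune, stress, metabolic, developmental and tissue marker genes, and each was tested with camera on the edgeR fit with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists. Camera with a correlation estimated per list was run beside it, on only the 3 residual degrees of freedom, which lowers its power. So was fry, which tests whether genes of a list move on balance in 1 direction without comparing them with other genes. Counts of list members that rose or fell are over all genes tested, and counts adjusted over the list alone are given beside them. The genes named are, first, the 6 protein-coding genes with the highest and the 6 with the lowest log2 fold change among called genes with a mean of at least 5 CPM and no overlap between the libraries of the groups compared. The second part is up to 4 called members of each called list, and the third is a fixed set of 30 genes that report on known responses. The text leaves out some of the second part and members of the third that were not called. A few list members outside the rule are named too, and they were chosen after their values were seen. These are hrg-6, R186.1, mrp-5, nlp-27, gpd-1, gpd-4, vit-1, snb-1, col-135, ugt-43, ugt-44, ugt-57, nas-37, gst-23 and unc-22, and hrg-2 in L2 vs L1.

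Calls shared by both comparisons with OP50 were set beside 20 simulations of unchanged groups against the same OP50 libraries and beside the overlap of independent lists. With 2 OP50 libraries the controls could not be split. For genes with 1 to 3 counts in a group, the ratio of counts scaled by library size is given with an exact 95% binomial interval, which covers counting error only. Alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter and a stricter filter of at least 5 CPM in at least 2 libraries. Others were nuclear protein-coding genes only, a minimum absolute log2 fold change of 1, fits of only the groups compared, a replicate block, and leaving out each library in turn. RLE and upper-quartile scaling for the lists were chosen after seeing the data.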

Results

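Gene expression was measured by RNA sequencing in whole 3-day-old Caenorhabditis elegans fed their standard bacterial food, Escherichia coli OP50, or the lactic acid bacterium Lactococcus lactis strain L1 or L2. The series title gives the aim as finding the genes that feeding on L. lactis regulates. OP50, L1 and L2 each had 2 libraries. Total counts ran from 17280251 in OP50 replicate 2 to 29336753 in L2 replicate 2, and 15600 genes were tested, which held 99.9% of the counts. The 6 yolk protein (vitellogenin) genes alone took 6.31% and 8.85% of the counts in the OP50 libraries, 2.20% and 2.58% in L1, and 4.08% and 4.16% in L2. Replicates correlated at 0.980 to 0.989 across genes, and libraries of different groups at 0.931 to 0.965. The OP50 libraries differed from each other in several lists. The 41 sperm genes were higher in replicate 1 by a median log2 difference of 1.52, with 40 of 41 higher, and 109 of the 146 cuticle collagens were higher in it by a median of 0.60. So were 16 of 18 SKN-1 targets (median 0.83), 35 of 44 glutathione S-transferases (0.60), 49 of 62 UDP-glycosyltransferases (0.56) and all 15 heat shock genes (0.52). The L2 libraries differed in the heat shock response, where all 15 genes were higher in replicate 1, by a median of 1.14.

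L1 vs OP50 asked which genes respond to strain L1. Worms on L1 had far more RNA of the genes for handling heme, more RNA of neuron and muscle genes, and less RNA of oocyte, early embryo and yolk protein genes. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3600 genes rose and 3083 fell of 15600, and 1946 of the former and 527 of the latter changed at least 2-fold. The median log2 fold change of all genes was 0.12, and the balance turned with RLE scaling (3250 rose and 3523 fell), with DESeq2 (3280 and 3445), in a fit of only the groups compared (2912 and 3063) and without L2 replicate 1 (2935 and 3103). Without L1 replicate 1 the number called dropped from 6683 to 3799. Of the 52 genes named for this comparison 50 were called, and 12 of these lost their call when some library was left out. Leaving out 1 library also moved the fold change of 12 of the 50 by more than 1.5-fold, and the count of called members by over 1.5 times in 6 of the 12 called lists. Camera called 12 of 46 lists, 8 up and 4 down, and none with an estimated correlation, where their adjusted p ran from 0.0935 to 0.999.

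All 8 genes of heme transport and homeostasis rose on L1, with a median log2 fold change of 3.83 (camera adjusted p = 6.18e-28; adjusted p = 0.0935 with an estimated correlation), and all 8 rose adjusted over the list alone. The gene hrg-2 (WBGene00010473, V:12409369-12410513, minus strand; positions on WBcel235), whose product binds heme in the hypodermis, went from 2.41 ± 0.00818 CPM on OP50 to 155 ± 3.49 CPM on L1 (SD, n = 2 libraries). This was a log2 fold change of 6.01 ± 0.13 (SE; edgeR adjusted p = 3.65e-07). The gene hrg-7 (WBGene00007605, V:12742041-12744207, plus strand), a protease relative that signals heme status between tissues, went from 31.3 ± 9.59 to 1411 ± 153 CPM, a log2 fold change of 5.49 ± 0.27 (edgeR adjusted p = 8.84e-05). The heme transporter hrg-1 (WBGene00019830, X:4008058-4016185, minus strand) rose by 4.26 ± 0.16 (edgeR adjusted p = 1.68e-05), from 2.94 ± 0.368 to 56.3 ± 3.56 CPM. Its intestinal relative hrg-4 rose by 3.39 ± 0.38 and the secreted heme carrier hrg-3 by 4.43 ± 0.47 (edgeR adjusted p = 0.00174 for both), from low counts on OP50 of 11 and 8 reads in all. The rise of hrg-3 ran from 3.72 without OP50 replicate 1 to 5.54 without OP50 replicate 2. The heme exporter mrp-5 rose by 1.58 ± 0.14 (edgeR adjusted p = 0.00110), R186.1 by 1.96 ± 0.23 (0.00177) and hrg-6 by 1.28 ± 0.41 (0.0345), and these 3 were chosen after their values were seen. The hrg-6 call ended when any library but OP50 replicate 1 was left out, with an adjusted p of up to 0.135.

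**Figure D1:**
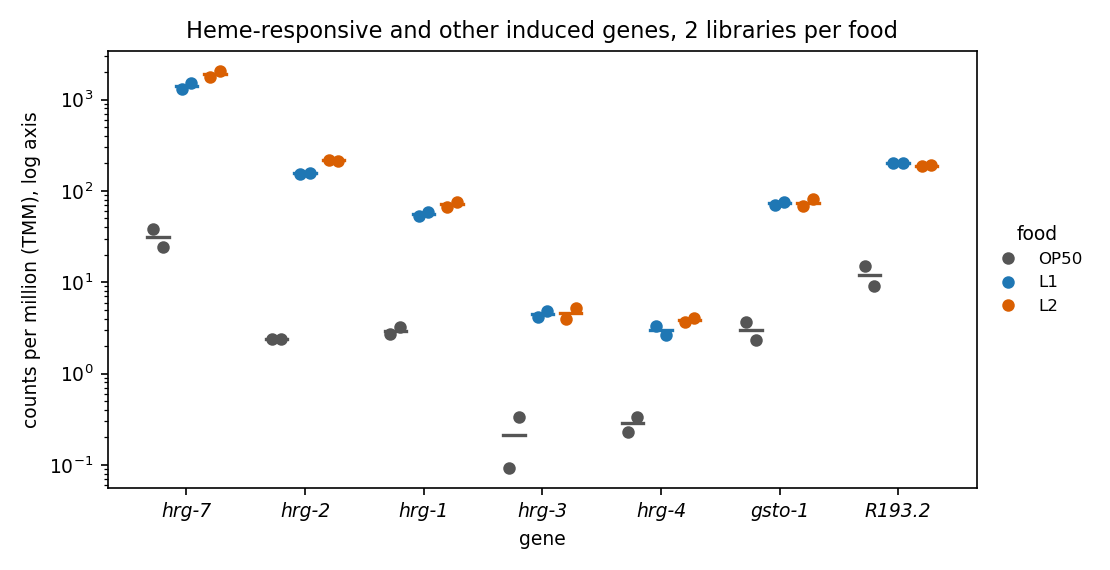
Expression in CPM on a log axis of 5 heme genes (hrg-7, hrg-2, hrg-1, hrg-3, hrg-4), gsto-1 and R193.2 on OP50, L1 and L2; each dot is a library and each bar a group mean. Expression of hrg-2 went from 2.41 CPM on OP50 to 155 CPM on L1 and 217 CPM on L2.

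The other genes with the largest rises on L1 were gsto-1, Y41C4A.32 and R193.2. The omega-class glutathione transferase gsto-1 (WBGene00016204, III:7945544-7947018, minus strand) rose by a log2 fold change of 4.57 ± 0.21 (edgeR adjusted p = 6.54e-05), from 3.03 ± 0.947 to 72.9 ± 3.09 CPM. R193.2 (WBGene00020128, X:1132993-1148585, minus strand) rose by 4.06 ± 0.23 (edgeR adjusted p = 5.03e-04), from 12.1 ± 4.37 to 203 ± 1.44 CPM. Y41C4A.32 (WBGene00270321, III:11721706-11723602, plus strand) rose by 4.36 ± 0.89 (edgeR adjusted p = 0.0190), a call that ended on leaving out any OP50 or L1 library, with an adjusted p of up to 0.171. Exons of gsto-1, hrg-7 and hrg-3 overlap an exon of a gene on the other strand. The same holds for other genes named below, such as eat-4, nit-1 and wrt-2. Exons of gst-4 overlap the gene dhs-12 on the same strand.

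Oocyte, early embryonic and yolk protein genes fell on L1. None of 41 sperm genes was called, also adjusted over the list alone (median 0.04, camera adjusted p = 0.846), but 40 of them were higher in OP50 replicate 1 (median 1.52) and 37 in L1 replicate 1 (0.61), so a change could have been missed. All 30 genes of the oocyte and eggshell fell, also adjusted over the list alone, by a median of -0.92 (camera adjusted p = 2.96e-20; adjusted p = 0.859 with an estimated correlation). The eggshell proteoglycan gene cpg-1 fell by 1.47 ± 0.18 in log2 (edgeR adjusted p = 0.00180), the eggshell gene perm-4 by 1.23 ± 0.17 (0.00199) and the oocyte maturation gene oma-1 (WBGene00003864, IV:8888976-8890999, plus strand) by 0.99 ± 0.15 (0.00236). Of 13 early embryonic genes 8 fell and none rose, the same adjusted over the list alone, by a median of -0.99 (camera adjusted p = 0.00127; adjusted p = 0.938 with an estimated correlation), and 5 fell without OP50 replicate 2. The T-box gene tbx-37, which specifies early blastomeres, fell by 2.71 ± 0.52 (edgeR adjusted p = 0.00518), from -3.49 without L1 replicate 2 to -2.18 without L1 replicate 1. Of the 6 vitellogenins, made in the intestine and taken up by oocytes, 5 fell, the same adjusted over the list alone, by a median of -1.57 (camera adjusted p = 1.16e-05; adjusted p = 0.368 with an estimated correlation), and 3 fell without L1 replicate 1. The largest fall was that of vit-5 (WBGene00006929, X:3403471-3408603, plus strand), by 2.47 ± 0.30 (edgeR adjusted p = 0.00180), and vit-6 fell by 1.80 ± 0.28 (0.00254). Also lower were vit-3 by 1.72 ± 0.30 (edgeR adjusted p = 0.00464), vit-2 by 1.23 ± 0.30 (0.0123) and vit-4 by 1.42 ± 0.39 (0.0304). The vit-2 call ended without L1 replicate 1 (0.0733), and that of vit-4 without OP50 replicate 1 or either L1 library (up to 0.182). The remaining gene, vit-1, chosen after its value was seen, did not pass (-1.19 ± 0.54, edgeR adjusted p = 0.138).

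Neuron, body wall muscle and pharynx markers rose on L1, while 17 intestine markers (5 rose and 1 fell, median 0.52, camera adjusted p = 0.405) and 18 hypodermis markers (7 rose and 3 fell, median 0.53, 0.651) were not called. Adjusted over the list alone the counts of those 2 lists were the same. Of 20 neuron markers 19 rose, and all 20 adjusted over the list alone, by a median of 1.17 (camera adjusted p = 3.01e-12; adjusted p = 0.655 with an estimated correlation). The neuronal identity gene unc-86 rose by 1.67 ± 0.22 in log2 (edgeR adjusted p = 0.00219) and the vesicular glutamate transporter eat-4 by 1.37 ± 0.17 (0.00185). Only snb-1, chosen after its value was seen, did not pass over all genes (0.28 ± 0.10, edgeR adjusted p = 0.0585). Among 99 neuropeptide genes 54 rose and 1 fell, 60 and 1 adjusted over the list alone, by a median of 0.76 (camera adjusted p = 2.79e-07; adjusted p = 0.999 with an estimated correlation), and 18 rose without L1 replicate 2. The peptide gene nlp-53 rose by 1.66 ± 0.21 (edgeR adjusted p = 0.00192) and flp-27 by 1.19 ± 0.16 (0.00208), and nlp-27, chosen after its value was seen, fell by 0.69 ± 0.16 (0.00929). Of 18 body wall muscle markers 16 rose, 17 adjusted over the list alone, by a median of 0.93 (camera adjusted p = 3.32e-06; adjusted p = 0.999 with an estimated correlation), and 9 rose without L1 replicate 2. The muscle myosin gene myo-3 rose by 1.36 ± 0.19 (edgeR adjusted p = 0.00207), from 635 ± 29.4 CPM, and the troponin T gene mup-2 by 1.19 ± 0.24 (0.00636). Of 20 pharynx markers 11 rose and 2 fell, 13 and 2 adjusted over the list alone, by a median of 1.06 (camera adjusted p = 0.00113; adjusted p = 0.999 with an estimated correlation), and 7 rose without OP50 replicate 2. The pharyngeal myosin gene myo-5 rose by 1.67 ± 0.20 (edgeR adjusted p = 0.00180), and the cuticle protein genes abu-6 and abu-7 fell by 3.97 ± 0.91 (0.0127) and 2.43 ± 0.55 (0.0108). The abu-7 call ended without OP50 replicate 1 or L1 replicate 2, with an adjusted p of up to 0.0585, and the abu-6 value ran from -9.26 without L1 replicate 1 to -3.12 without OP50 replicate 1.

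Of 28 autophagy and lysosome genes 16 rose and none fell, 17 and none adjusted over the list alone, by a median of 0.54 (camera adjusted p = 0.00193; adjusted p = 0.428 with an estimated correlation). Among them were the proton pump subunit vha-5, up by 1.07 ± 0.16 (edgeR adjusted p = 0.00256), and the lysosomal regulator hlh-30, up by 1.01 ± 0.15 (0.00239). Of 10 hypoxia response genes 7 rose, the same adjusted over the list alone, by a median of 0.71 (camera adjusted p = 0.00210; adjusted p = 0.655 with an estimated correlation). They included the HIF-1 target nhr-57, up by 1.33 ± 0.15 (edgeR adjusted p = 0.00174), and the sulfide oxidase sqrd-1, up by 0.97 ± 0.15 (0.00267). Of 24 genes of glycolysis and gluconeogenesis 12 rose and 2 fell, 14 and 2 adjusted over the list alone, by a median of 0.44 (camera adjusted p = 0.0430; adjusted p = 0.999 with an estimated correlation). The gluconeogenic pck-1 and the lactate dehydrogenase ldh-1 rose by 1.199 ± 0.138 (edgeR adjusted p = 0.00177) and 1.196 ± 0.134 (0.00174). The isoenzyme genes gpd-4 and gpd-1 fell by 0.68 ± 0.14 (0.00612) and 0.76 ± 0.16 (0.00854) and were chosen after their values were seen. The glycolysis call ended without L1 replicate 2 (camera adjusted p = 0.340, 4 rose), OP50 replicate 2 (0.0706), L2 replicate 1 (0.110) or L2 replicate 2 (0.0590), and with RLE scaling (0.0570).

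Of 12 targets of the p38 immune pathway 4 fell and none rose on L1, the same adjusted over the list alone. The list was called down (camera adjusted p = 0.0430; adjusted p = 0.999 with an estimated correlation) with a mean log2 fold change of -0.50, although its median was 0.07. The call ended without OP50 replicate 1 (0.194) or L1 replicate 1 (0.0808) and with RLE scaling (0.0536). The immune reporter T24B8.5 (WBGene00011979, II:9082626-9083146, minus strand) fell by 3.24 ± 0.48 (edgeR adjusted p = 0.00372), from 29.2 ± 1.76 to 3.14 ± 2.33 CPM, with a value from -4.35 without L1 replicate 2 to -2.61 without L1 replicate 1. The other 3 were C17H12.8, which fell by 2.22 ± 0.19 (edgeR adjusted p = 0.00129), K08D8.5 by 1.93 ± 0.30 (0.00286) and the lectin gene clec-85 by 1.58 ± 0.15 (0.00145). The stearoyl desaturase gene fat-7 rose by 1.38 ± 0.35 (edgeR adjusted p = 0.0203), a call that ended on leaving out any OP50 or L1 library (up to 0.116). The ferritin gene ftn-1, which stores iron, fell by 0.87 ± 0.22 (edgeR adjusted p = 0.0159), which ended without OP50 replicate 2 or L1 replicate 2 (up to 0.0753).

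Cuticle genes moved both ways on L1. Of the 146 collagens 17 rose and 21 fell, 8 and 8 adjusted over the list alone (camera adjusted p = 0.998), with a median of 0.34 and a mean of -0.04. Collagen genes were 4 of the 6 lowest genes named. Expression of col-41 fell by 3.59 ± 0.72 in log2 (edgeR adjusted p = 0.0183), col-73 changed by -3.997 ± 0.894 (0.0247) and col-161 by -3.90 ± 1.09 (0.0449). The body shape gene dpy-4 (WBGene00001066, IV:14985543-14986784, minus strand), also a collagen gene, fell by 3.40 ± 0.81 (edgeR adjusted p = 0.0289), and T06E4.12 by 3.44 ± 0.80 (0.0205). All 5 calls ended on leaving out either L1 library, with an adjusted p of up to 0.180 for col-41, 0.223 for col-73, 0.170 for col-161, 0.244 for dpy-4 and 0.0834 for T06E4.12. The OP50 libraries differed widely in these genes (354 ± 271 CPM for dpy-4). Only K02E11.10 (WBGene00044109, V:14239942-14241151, minus strand), a gene without a known role, kept its call whichever library was left out. K02E11.10 fell by 5.24 ± 0.61 (edgeR adjusted p = 0.00234), from 1334 reads on OP50 to 45 on L1, with a value of -4.37 without OP50 replicate 1.

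L2 vs OP50 asked which genes respond to strain L2. Worms on L2 had a rise of the heme genes of about the size on L1. They also had more RNA of glutathione transferases and other targets of the oxidative stress regulator SKN-1, and less RNA of collagen, molting and yolk protein genes. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 719 genes rose and 604 fell of 15600, 332 and 512 of them by at least 2-fold, and the median of all genes was 0.01. The count of 1323 dropped to 278 without L2 replicate 2 (166 rose and 112 fell) and to 664 without L2 replicate 1 (173 and 491). The balance also turned without OP50 replicate 2 (394 and 543) or L1 replicate 2 (513 and 544), in a fit of only the groups compared (513 and 554), with RLE scaling (653 and 661) and with DESeq2 (949 and 999), and was even without a filter (1440 and 1440). Of 53 genes named for this comparison 50 were called, and 28 of these lost their call when some library was left out. Leaving out 1 library also moved the fold change of 19 of the 50 by more than 1.5-fold, and the count of called members by over 1.5 times in 23 of the 26 called lists. Camera called 26 of 46 lists, 17 up and 9 down, of which only the heme genes held with an estimated correlation. The adjusted p of the other lists was at least 0.370 with it.

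Of the 8 heme genes 7 rose on L2, the same adjusted over the list alone, with a median log2 fold change of 4.11 (camera adjusted p = 1.60e-61; adjusted p = 0.0345 with an estimated correlation). Expression of hrg-2 rose by 6.49 ± 0.13 (edgeR adjusted p = 2.17e-07) to 217 ± 3.83 CPM and hrg-7 by 5.93 ± 0.28 (5.92e-05) to 1913 ± 234 CPM (SD, n = 2 libraries). The transporter hrg-1 rose by 4.60 ± 0.16 (edgeR adjusted p = 9.57e-06), hrg-3 by 4.46 ± 0.47 (0.00275) and hrg-4 by 3.76 ± 0.37 (0.00223). Chosen after their values were seen, R186.1 rose by 1.96 ± 0.23 (edgeR adjusted p = 0.00390), mrp-5 rose by 1.66 ± 0.14 (0.00121) and hrg-6 did not pass (0.67 ± 0.42, 0.378). The glutathione transferase gsto-1 rose by 4.61 ± 0.21 (edgeR adjusted p = 5.92e-05). Y41C4A.32 rose by 5.43 ± 0.91 (edgeR adjusted p = 0.0378), a call that ended on leaving out any OP50 or L1 library (up to 0.273). B0205.13 (WBGene00044644, I:10727755-10728808, minus strand), a gene without a known role, rose by 4.79 ± 0.50 (edgeR adjusted p = 0.00519), from 1.03 ± 0.827 to 29.7 ± 10.1 CPM, with a value from 4.195 without OP50 replicate 2 to 6.03 without OP50 replicate 1. The value of hrg-3 likewise ran from 3.76 without OP50 replicate 1 to 5.57 without OP50 replicate 2.

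Glutathione S-transferases and SKN-1 targets rose on L2, while the 70 cytochrome P450s, another detoxification family, were not called (7 rose and 1 fell, the same adjusted over the list alone, camera adjusted p = 0.0539). Of 44 glutathione S-transferases 21 rose, 27 adjusted over the list alone, by a median of 1.33 (camera adjusted p = 5.05e-21; adjusted p = 0.375 with an estimated correlation). Of 18 SKN-1 targets, 10 of which are also in that list, 13 rose, 15 adjusted over the list alone, by a median of 1.92 (camera adjusted p = 2.62e-23; adjusted p = 0.373 with an estimated correlation). No gene of either list fell. Without L2 replicate 1, 13 glutathione S-transferases and 8 SKN-1 targets rose, and both lists were higher in OP50 replicate 1 than in OP50 replicate 2, by a median of 0.60 and 0.83. Expression of gst-30 (WBGene00001778, II:4933883-4935038, minus strand) rose by 4.58 ± 0.51 in log2 (edgeR adjusted p = 0.00467), gst-12 (WBGene00001760, II:13616685-13618061, minus strand) by 4.17 ± 0.49 (0.00966) and gst-14 by 3.39 ± 0.32 (0.00223). Without OP50 replicate 1 the values of gst-30 and gst-12 were 5.36 and 5.04, and that of gst-30 was 3.88 without L2 replicate 1. The SKN-1 reporter gst-4 (WBGene00001752, IV:10142135-10143099, plus strand) went from 21.01 ± 12.54 to 271 ± 55.9 CPM, a rise of 3.68 ± 0.46 (edgeR adjusted p = 0.0185) that ended on leaving out either L1 library (up to 0.0795). The glutathione synthesis gene gcs-1 rose by 0.83 ± 0.16 (edgeR adjusted p = 0.0201), which ended without OP50 replicate 2 or L2 replicate 1 (up to 0.175). Of 62 UDP-glycosyltransferases 11 rose and 3 fell, 15 and 4 adjusted over the list alone, by a median of 0.34 (camera adjusted p = 7.10e-04; adjusted p = 0.602 with an estimated correlation). Without L2 replicate 2, 5 rose. Here ugt-13 rose by 2.65 ± 0.33 (edgeR adjusted p = 0.00995), and by 3.33 without OP50 replicate 1. The 3 that fell, chosen after their values were seen, were ugt-43 by 1.96 ± 0.33 (0.0138), ugt-44 by 2.19 ± 0.25 (0.00416) and ugt-57 by 0.97 ± 0.22 (0.0325). Each of these 3 calls ended without L2 replicate 2, with an adjusted p of 0.0853 for ugt-43, 0.0504 for ugt-44 and up to 0.137 for ugt-57.

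Genes for the cuticle fell on L2. Of 19 molting genes 12 fell, 15 adjusted over the list alone, by a median of -1.94 (camera adjusted p = 5.24e-28; adjusted p = 0.370 with an estimated correlation). Of 146 cuticle collagens 36 fell and 1 rose, 65 and 3 adjusted over the list alone, by a median of -1.32 (camera adjusted p = 1.94e-21; adjusted p = 0.410 with an estimated correlation). Without L2 replicate 2, 14 collagens and 8 molting genes fell. The 18 hypodermis markers, 9 of which are collagens of that list, had 9 that fell and none that rose, 10 and 1 adjusted over the list alone, and a median of -1.45 (camera adjusted p = 2.71e-09; adjusted p = 0.410 with an estimated correlation), and 5 fell without OP50 replicate 1. The molting gene mlt-10 (WBGene00015646, II:546705-552031, plus strand) fell by 2.28 ± 0.14 in log2 (edgeR adjusted p = 2.55e-04), from 67.7 ± 3.84 to 13.9 ± 1.15 CPM. Larger falls rested on OP50 libraries that differed widely: dpy-4 fell by 7.137 ± 0.997 (edgeR adjusted p = 0.0258) from 354 ± 271 to 2.45 ± 2.07 CPM. The collagen genes dpy-13 (WBGene00001074, IV:4235614-4236710, plus strand), rol-6 and col-73 fell by 6.96 ± 0.99 (edgeR adjusted p = 0.0267), 5.81 ± 0.77 (0.0231) and 7.91 ± 1.16 (0.0288). T06E4.12 fell by 7.182 ± 1.099 (edgeR adjusted p = 0.0230). All 5 calls ended without L2 replicate 1, with an adjusted p of up to 0.192 for dpy-4, 0.211 for dpy-13, 0.141 for rol-6, 0.275 for col-73 and 0.196 for T06E4.12. K02E11.10 had 3 reads on L2 against 1334 on OP50, a ratio per library size of OP50 over L2 of 610 (exact 95% interval 208 to 2963). Y48G8AL.12 had 3 against 731, a ratio of 334 (114 to 1625). These intervals cover counting error only and leave out the spread between replicates. The collagen gene col-135, chosen after its value was seen, rose by 1.45 ± 0.27 (edgeR adjusted p = 0.0263), which ended without L2 replicate 2 (0.109).

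Of the 6 vitellogenins 4 fell on L2, the same adjusted over the list alone, by a median of -1.34 (camera adjusted p = 1.19e-05; adjusted p = 0.370 with an estimated correlation), and none without L2 replicate 2. They were vit-3 by 1.70 ± 0.30 (edgeR adjusted p = 0.0194), vit-5 by 1.52 ± 0.29 (0.0206), vit-6 by 1.16 ± 0.27 (0.0370) and vit-4 by 1.82 ± 0.40 (0.0460), and all 4 calls ended without L2 replicate 2 (up to 0.0688, 0.149, 0.247 and 0.108). Neither vit-2 (-0.36 ± 0.29, edgeR adjusted p = 0.511) nor vit-1 (-1.04 ± 0.53, 0.326, chosen after its value was seen) passed. Oocyte genes, all lower on L1, had no called member on L2 (median -0.11, camera adjusted p = 0.0539). Of 15 heat shock genes 3 fell and none rose, 7 and none adjusted over the list alone, by a median of -0.86 (camera adjusted p = 6.28e-06; adjusted p = 0.602 with an estimated correlation). None fell without OP50 replicate 1 and 9 fell without L2 replicate 1, libraries in which all 15 genes were above their replicate, by a median of 0.52 and 1.14. The small heat shock genes hsp-16.2 and hsp-16.41 changed by -2.06 ± 0.43 (edgeR adjusted p = 0.0460) and -2.103 ± 0.409 (0.0403), and either call ended on leaving out any OP50 or L1 library (up to 0.212 and 0.204). The immune reporter T24B8.5 fell by 2.504 ± 0.454 (edgeR adjusted p = 0.0262), which ended on leaving out any OP50 or L2 library (up to 0.181).

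Of 99 neuropeptide genes 27 rose and none fell on L2, 50 and 2 adjusted over the list alone, by a median of 0.68 (camera adjusted p = 4.06e-13; adjusted p = 0.572 with an estimated correlation), and 3 rose without L2 replicate 2. The feeding-related flp-18 rose by 1.18 ± 0.14 (edgeR adjusted p = 0.00416). Of 20 neuron markers 8 rose, 16 adjusted over the list alone, by a median of 0.48 (camera adjusted p = 2.02e-07; adjusted p = 0.556 with an estimated correlation), and none without L2 replicate 1. Of 24 glycolysis genes 8 rose, 9 adjusted over the list alone, by a median of 0.27 (camera adjusted p = 4.01e-04; adjusted p = 0.572 with an estimated correlation), and 1 without L2 replicate 1. The aldolase aldo-1 rose by 1.33 ± 0.19 (edgeR adjusted p = 0.00806). Of 10 hypoxia genes 3 rose and 1 fell, 7 and 1 adjusted over the list alone, by a median of 0.45 (camera adjusted p = 6.20e-04; adjusted p = 0.375 with an estimated correlation). The HIF-1 targets nit-1, which is also in the list of SKN-1 targets, and cysl-2 rose by 1.95 ± 0.15 (edgeR adjusted p = 9.10e-04) and 0.90 ± 0.11 (0.00459). The collagen hydroxylase gene phy-2 fell by 1.46 ± 0.29 (0.0345), which ended on leaving out any OP50 or L2 library (up to 0.168). The desaturase gene fat-7 rose by 2.496 ± 0.354 (edgeR adjusted p = 0.0133), which ended on leaving out either OP50 library (up to 0.0806). The superoxide dismutase gene sod-3 rose by 1.68 ± 0.32 (edgeR adjusted p = 0.0214), which ended on leaving out either L2 library (up to 0.0809), and ftn-1 fell by 1.12 ± 0.22 (0.0234), which ended without OP50 replicate 2 or either L2 library (up to 0.150).

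The other 13 lists called for L2 had medians between -0.79 and 0.47. Their calls ended when 1 library was left out, and with an estimated correlation their adjusted p was 0.375 or more. Without OP50 replicate 1 the calls ended for mitochondrially encoded genes (median -0.41, 2 of 12 fell; camera adjusted p from 0.00190 to 0.0727), iron and metal handling (0.43, 4 of 15 rose and 1 fell; 0.00958 to 0.0780) and the infection response (0.47, 3 of 14 rose; 0.00958 to 0.0780). They also ended for fatty acid oxidation (-0.27, 2 of 21 fell; 0.0176 to 0.191) and for sperm genes (-0.79, none of 41 called; 0.00822 to 0.747). The sperm median became 0.34. Without OP50 replicate 2 they ended for ribosomal proteins (0.24, 1 of 80 fell; 0.00316 to 0.561), muscle markers (0.45, none of 18 called; 0.00329 to 0.118) and early embryonic genes (-0.45, 3 of 13 fell; 0.0106 to 0.195). They ended there too for the mitochondrial unfolded protein response (0.34, 2 of 10 rose; 0.0238 to 0.126), insulin-like peptides (0.40, 2 of 25 rose; 0.0276 to 0.345) and fatty acid desaturases and elongases (0.41, 2 of 18 rose and 1 fell; 0.0297 to 0.0852). Without L2 replicate 1 the autophagy and lysosome call ended (0.24, 3 of 28 rose; 0.0198 to 0.0903), and without L2 replicate 2 that of intestinal proteases (0.19, 3 of 18 rose and 1 fell; 0.0108 to 0.0511). Each of these lists had at most 1 called member in its direction with some library left out. Adjusted over each list alone, 5 mitochondrially encoded genes fell, 5 metal genes rose and 1 fell, 6 infection genes rose, 5 oxidation genes fell, and 4 early embryonic genes fell. In the same way 5 genes of the unfolded protein response, 4 of autophagy and 4 desaturases or elongases rose, with 1 of the last that fell, 7 insulin-like genes rose and 2 fell, and 7 proteases rose and 1 fell. No sperm, muscle or ribosomal protein gene passed over its list alone.

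Members of these lists that changed on L2 included the cadmium response gene cdr-4, up by 1.81 ± 0.22 in log2 (edgeR adjusted p = 0.00452), and the protease gene asp-8, up by 1.303 ± 0.171 (0.00583). The metal transporter smf-3 rose by 1.51 ± 0.26 (edgeR adjusted p = 0.0155) and the elongase elo-4 fell by 2.04 ± 0.33 (0.0117), calls that ended without L2 replicate 2 (0.0909 and 0.0916). The lectin gene clec-52 rose by 2.04 ± 0.29 (edgeR adjusted p = 0.0143), which ended on leaving out either OP50 library or L2 replicate 2 (up to 0.0976). The protease gene cpr-6 fell by 0.55 ± 0.13 (edgeR adjusted p = 0.0370), which ended on leaving out any OP50 or L2 library (up to 0.195). The ribosomal protein gene rpl-41.1 fell by 0.89 ± 0.21 (edgeR adjusted p = 0.0393), which ended on leaving out any library but OP50 replicate 1 (up to 0.208).

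**Figure D2:**
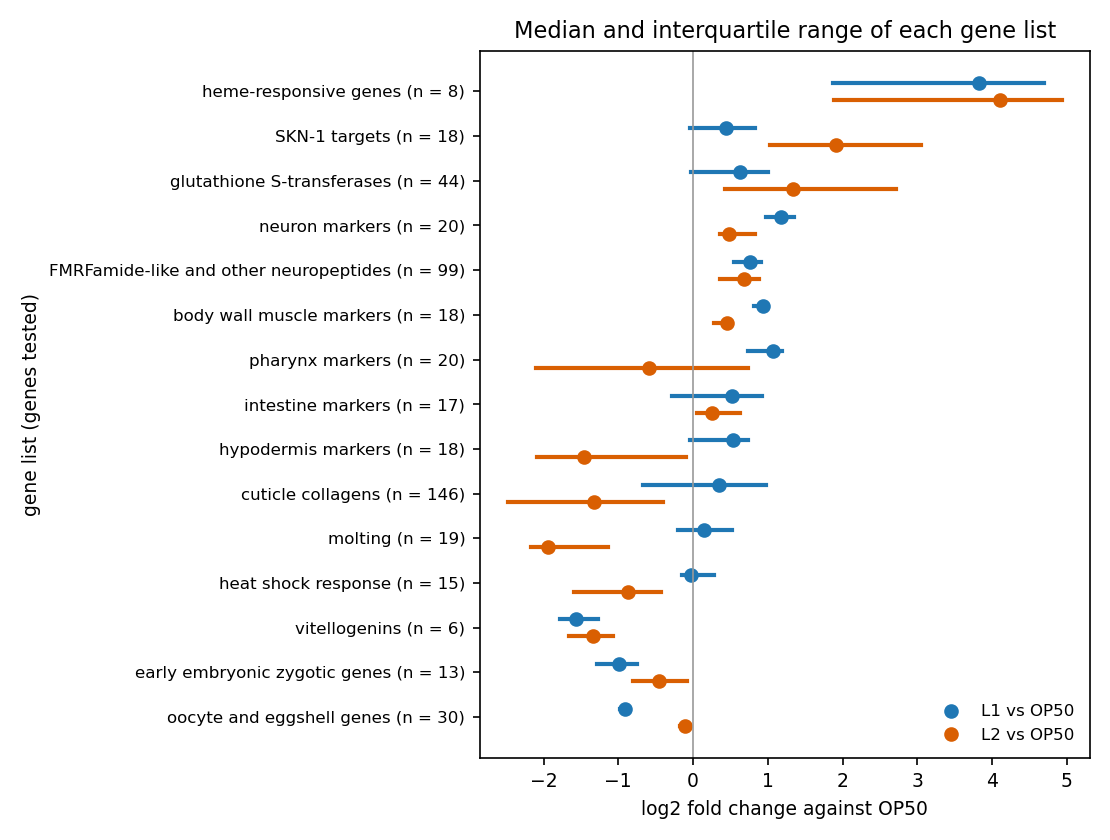
Median log2 fold change (points) and interquartile range (bars) of the genes of 15 lists on L1 (blue) and L2 (orange), each against OP50. The heme genes had medians of 3.83 and 4.11, and the molting genes of 0.15 and -1.94.

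L2 vs L1 asked where the strains differ. Worms on L2 had more RNA of oocyte genes and glutathione transferases than worms on L1. They had less of collagen, molting, pharynx and neuron genes and of 5 of 18 muscle markers, while the heme genes differed little. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 2638 genes were higher and 2824 lower on L2 of 15600, 218 and 1659 of them by at least 2-fold, and the balance turned with RLE scaling (2878 and 2706) and with DESeq2 (2871 and 2764). The count of 5462 dropped to 691 without L2 replicate 2, 1919 without L1 replicate 1 and 3584 without L2 replicate 1. Of 42 genes named for this comparison 40 were called, and 29 of these lost their call when some library was left out. Leaving out 1 library also moved the difference of 12 of the 40, as a ratio, by more than 1.5-fold, and the count of called members by over 1.5 times in 8 of the 10 called lists. Camera called 10 of 46 lists, 3 up and 7 down, and none with an estimated correlation, where each had an adjusted p of 0.926.

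All 30 oocyte and eggshell genes were higher on L2 than on L1, also adjusted over the list alone, by a median of 0.80 (camera adjusted p = 4.59e-16; adjusted p = 0.926 with an estimated correlation), but only 1 of them without L2 replicate 2. The maternal RNA regulator genes mex-6, pos-1 and oma-1 were higher by 0.95 ± 0.14 (edgeR adjusted p = 0.00404), 0.94 ± 0.14 (0.00428) and 0.87 ± 0.15 (0.00480), calls that ended without L2 replicate 2 (0.0510, 0.0552 and 0.0596). Expression of vit-2 was higher by 0.87 ± 0.29 (edgeR adjusted p = 0.0497), which ended on leaving out any L1 or L2 library (up to 0.237). Of 18 SKN-1 targets 10 were higher and none lower, 12 and 1 adjusted over the list alone, by a median of 1.25 (camera adjusted p = 8.47e-09; adjusted p = 0.926 with an estimated correlation). Of 44 glutathione S-transferases 16 were higher and 1 lower, the same adjusted over the list alone, by a median of 0.82 (camera adjusted p = 1.50e-06; adjusted p = 0.926 with an estimated correlation). The largest differences were in gst-30, by 4.19 ± 0.48 in log2 (edgeR adjusted p = 0.00318), gst-12 by 3.41 ± 0.46 (0.00477) and gst-14 by 2.63 ± 0.30 (0.00289). Without L1 replicate 1, 8 glutathione S-transferases were higher, and without L2 replicate 1 the gst-30 difference was 3.57. Expression of gst-4 was higher by 3.45 ± 0.46 (edgeR adjusted p = 0.00687), which ended without L1 replicate 1 (0.0975), and gcs-1 by 0.97 ± 0.16 (0.00458). The 1 lower member, gst-23, chosen after its value was seen, was lower by 1.03 ± 0.35 (edgeR adjusted p = 0.0489), which ended without L2 replicate 2 or either L1 library (up to 0.288). B0205.13 was higher by 3.32 ± 0.44 (edgeR adjusted p = 0.00429), and W06H8.2 (WBGene00021066, V:6206755-6208551, plus strand) by 3.04 ± 0.46 (0.00605), which ended without L1 replicate 1 (0.0802).

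**Figure D3:**
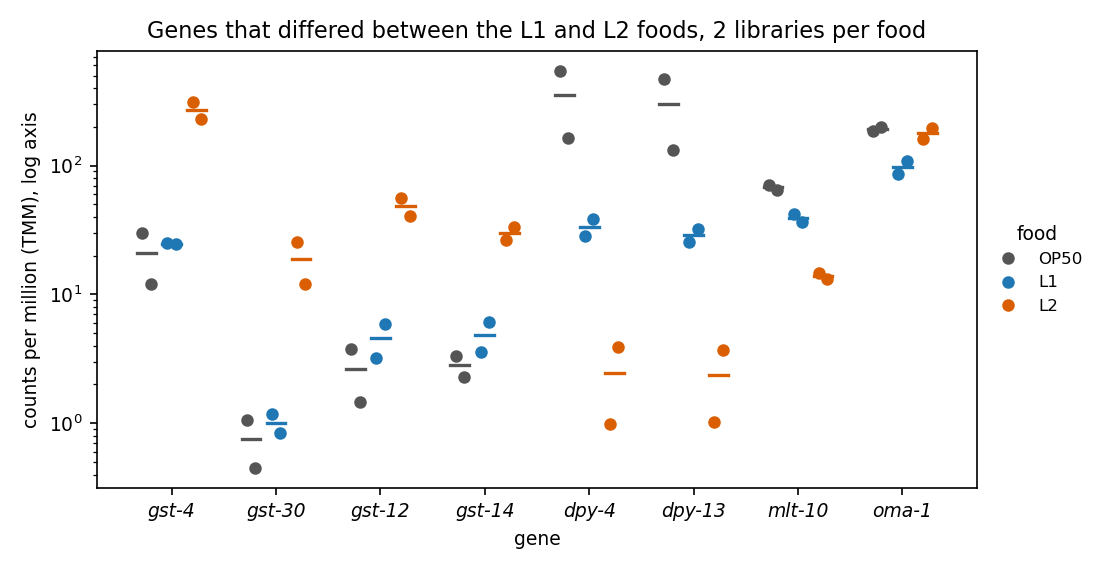
Expression in CPM on a log axis of 4 glutathione S-transferase genes (gst-4, gst-30, gst-12, gst-14), the cuticle genes dpy-4, dpy-13 and mlt-10 and the oocyte gene oma-1; each dot is a library and each bar a group mean. Expression of gst-4 was 24.8 CPM on L1 and 271 CPM on L2.

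Of 19 molting genes 15 were lower and 1 higher on L2 than on L1, 16 and 1 adjusted over the list alone, by a median of -1.93 (camera adjusted p = 2.24e-14; adjusted p = 0.926 with an estimated correlation). Expression of mlt-9 was lower by 3.25 ± 0.37 (edgeR adjusted p = 0.00423) and ptr-4 by 2.77 ± 0.22 (0.00170). The astacin protease gene nas-37, chosen after its value was seen, was higher by 0.74 ± 0.16 (edgeR adjusted p = 0.00994), which ended without L1 replicate 1 or either L2 library (up to 0.0704). Of 146 collagens 64 were lower and 1 higher, 69 and 1 adjusted over the list alone, by a median of -1.69 (camera adjusted p = 4.42e-13; adjusted p = 0.926 with an estimated correlation), and 22 were lower without L1 replicate 1. The collagen gene dpy-13 was lower by 3.57 ± 0.90 (edgeR adjusted p = 0.0399), which ended on leaving out any L1 or L2 library (up to 0.217), and col-135, chosen after its value was seen, was higher by 1.76 ± 0.27 (0.00552). Of 18 hypodermis markers 10 were lower, 12 adjusted over the list alone, by a median of -1.82 (camera adjusted p = 2.59e-08; adjusted p = 0.926 with an estimated correlation), and 6 were lower without L1 replicate 1. The hedgehog-related wrt-2 was lower by 3.24 ± 0.35 (edgeR adjusted p = 0.00375). Its exons overlap the gene pccb-1 on the other strand, which had a mean count of 11155 per library. Of 20 pharynx markers 14 were lower, 15 adjusted over the list alone, by a median of -1.64 (camera adjusted p = 7.71e-07; adjusted p = 0.926 with an estimated correlation), and 4 were lower without L1 replicate 1. The pharyngeal gland gene phat-1 was lower by 3.47 ± 0.53 (edgeR adjusted p = 0.00675), with a value of -4.51 without L2 replicate 1 and -2.83 without L2 replicate 2. The abu-7 gene had 3 reads on L2 and 49 on L1, a ratio per library size of L1 over L2 of 16.8 (exact 95% interval 5.42 to 84.2), and its call ended without L1 replicate 1 or either L2 library (up to 0.108).

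Of 20 neuron markers 13 were lower on L2 than on L1, 15 adjusted over the list alone, by a median of -0.59 (camera adjusted p = 9.46e-04; adjusted p = 0.926 with an estimated correlation), and none without L2 replicate 2. The synaptic gene unc-13 was lower by 1.03 ± 0.17 (edgeR adjusted p = 0.00517), which ended without L2 replicate 2 (0.0627), and unc-86 by 1.04 ± 0.22 (0.0102), which ended without that library or L1 replicate 1 (up to 0.0962). Of 15 heat shock genes 8 were lower, 11 adjusted over the list alone, by a median of -1.396 (camera adjusted p = 0.00324; adjusted p = 0.926 with an estimated correlation), a call that ended without L1 replicate 2 (0.0702), and none was lower without L1 replicate 1. Expression of hsp-16.2 was lower by 1.89 ± 0.42 (edgeR adjusted p = 0.0218) and the HSP70 gene F44E5.4 by 1.65 ± 0.43 (0.0296), and either call ended without L2 replicate 2 (up to 0.143 and 0.127). Of 18 muscle markers 5 were lower, the same adjusted over the list alone, by a median of -0.52 (camera adjusted p = 0.0125; adjusted p = 0.926 with an estimated correlation), a call that ended without L1 replicate 2 (0.107) or L2 replicate 2 (0.113), and none was lower without L1 replicate 1. These 5 were the giant protein gene ttn-1, by 0.87 ± 0.18 (edgeR adjusted p = 0.00929), myo-3 by 0.73 ± 0.18 (0.0176), unc-89 by 0.80 ± 0.21 (0.0237), dim-1 by 0.79 ± 0.22 (0.0303) and unc-22, chosen after its value was seen, by 0.63 ± 0.19 (0.0372). All 5 calls ended without L2 replicate 2, with an adjusted p of up to 0.0827, 0.187, 0.161, 0.218 and 0.289.

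Among the lowest genes on L2 against L1 was jud-4 (WBGene00007262, X:15284182-15286227, plus strand), a hypodermal gene, by 3.86 ± 0.45 (edgeR adjusted p = 0.00314), from 10.6 ± 4.47 to 0.733 ± 0.179 CPM. The pharyngeal abu-1 was lower by 4.03 ± 0.81 (edgeR adjusted p = 0.0146), grd-14 by 3.94 ± 0.88 (0.0278) and T06E4.10 by 3.83 ± 0.68 (0.0146), and each call ended without L1 replicate 1 (up to 0.114, 0.166 and 0.115). Y48G8AL.12 had 3 reads on L2 and 134 on L1, a ratio per library size of L1 over L2 of 45.9 (exact 95% interval 15.4 to 225), with a call that ended without L2 replicate 2 (0.0510). K02E11.10 had 3 and 45, a ratio of 15.4 (4.95 to 77.5), with a call that ended on leaving out any L1 or L2 library (up to 0.209). The desaturase genes fat-7 and fat-5 were higher by 1.12 ± 0.33 (edgeR adjusted p = 0.0395) and 0.67 ± 0.18 (0.0240), sod-3 by 0.93 ± 0.31 (0.0481) and the insulin-like ins-7 by 1.62 ± 0.54 (0.0486). These 4 calls ended on leaving out either L1 library or L2 replicate 1 (up to 0.226, 0.196, 0.206 and 0.326). Of the 8 heme genes 1, hrg-2, was higher on L2 than on L1, by 0.48 ± 0.096 (edgeR adjusted p = 0.00773), and the list had a median difference of 0.21 (camera adjusted p = 0.369). The hrg-2 gene was chosen after its value was seen, and its call ended without L1 replicate 1 or either L2 library (up to 0.0674). The 95% intervals of the difference were -0.07 to 0.95 for hrg-7 (edgeR adjusted p = 0.160) and 0.05 to 0.63 for hrg-1 (0.0696).

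Calls of both strains against OP50 overlapped more than independent lists among the genes that rose and little more among those that fell. Of the genes called against OP50, 579 rose and 141 fell on both strains, against 165.9 and 119.4 for independent lists, and 109 went in opposite directions, against 281. Both comparisons use the same OP50 libraries, which adds to the overlap by an amount that these counts do not show. In simulations of unchanged groups, which yield almost no calls, at most 2 genes were called higher and 1 lower in both, so they set no level for lists of this size. Only on L1 were 5854 genes called, and 3792 of these also differed between L2 and L1. Only on L2 were 494 called, with 419 that differed. These genes were picked by calls from the same L1 and L2 libraries, so part of these counts is built in. Log2 fold changes of both comparisons correlated at 0.405 across genes, against 0.523 in the simulations, and 67.2% of genes had the same sign in both data and simulations. The simulations hold no effects, so the shared OP50 libraries alone set their values. Effects of only 1 strain can lower both measures in the data, so these do not decide whether the strains agree beyond shared controls. The covariance was 0.282, against a median of 0.0650 and at most 0.0682 in the simulations. It was thus larger than in the simulations of unchanged groups. The covariance rose to 0.592 without OP50 replicate 1 and to 0.493 without OP50 replicate 2. Without an L1 or L2 library it ran from 0.263 to 0.411. It thus depended on the OP50 libraries, and whether the simulations match their spread was not tested. The covariance therefore does not decide either whether the strains agree beyond shared controls. The shared count of 720 dropped to 162 without L2 replicate 2, 189 without L2 replicate 1, 393 without L1 replicate 2 and 441 without OP50 replicate 2. Opposite calls ran from 20 without L2 replicate 2 to 184 without L1 replicate 2 and were 217 with DESeq2. Genes lower on both strains numbered 35 without L2 replicate 2 and 240 with DESeq2.

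**Figure D4:**
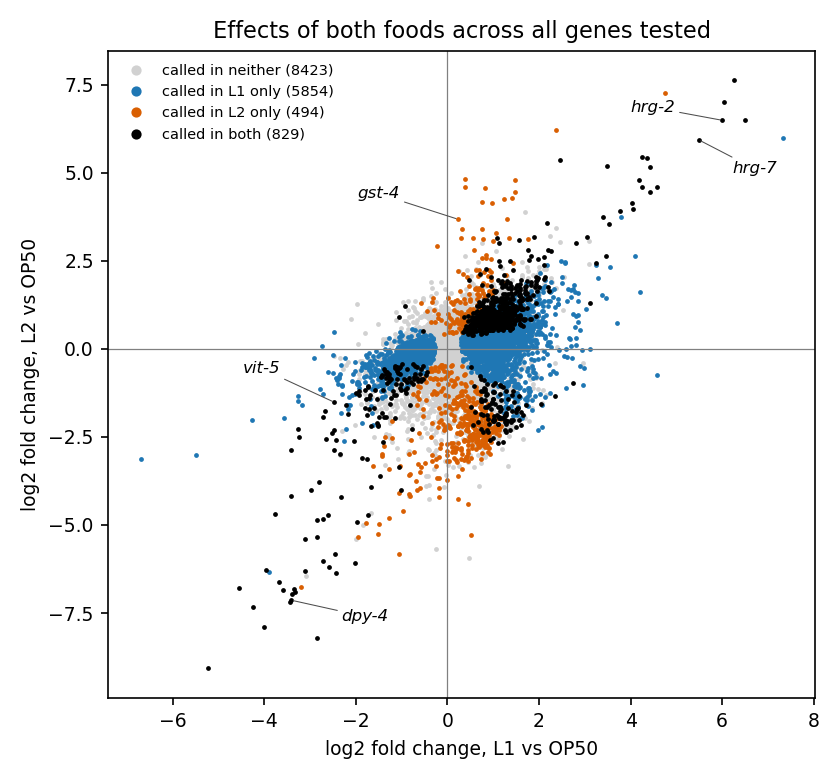
Log2 fold change of all 15600 genes on L1 (x axis) and L2 (y axis), each against OP50; each point is a gene and colors mark calls. Calls were made in neither comparison for 8423 genes, on L1 only for 5854, on L2 only for 494 and on both for 829, and genes without OP50 counts sit at fitted values.

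The mean of the L1 and L2 groups was compared with OP50 to rank genes by their average response, which 1 strain alone can carry. Molting genes were called on L2 and not on L1, oocyte genes on L1 and not on L2, and SKN-1 targets and glutathione S-transferases on L2 and not on L1. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment 2205 genes rose and 1858 fell, a balance that turned with RLE scaling (1978 and 2410), with DESeq2 (2194 and 2474) and without L2 replicate 1 (948 and 1197) or L1 replicate 2 (1538 and 1648). The count of 4063 dropped to 1725 without OP50 replicate 2, 2145 without L2 replicate 1 and 2636 without L2 replicate 2. Camera called 20 of 46 lists, 12 up and 8 down, of which the heme genes held with an estimated correlation (adjusted p = 0.0436; the others at least 0.210). Leaving out 1 library moved the count of called members by over 1.5 times in 12 of the 20. Of the 8 heme genes 7 rose, 8 adjusted over the list alone, by a median of 4.003 (camera adjusted p = 9.37e-49). SKN-1 targets had a median of 1.27 (10 of 18 rose, 13 adjusted over the list alone; camera adjusted p = 4.76e-09), glutathione S-transferases of 1.06 (20 of 44 rose, 23 over the list alone; 4.54e-09) and neuron markers of 0.88 (19 of 20 rose, 19 over the list alone; 3.96e-13). Vitellogenins had a median of -1.55 (5 of 6 fell, 5 over the list alone; camera adjusted p = 2.31e-08), molting genes of -0.78 (11 of 19 fell and 1 rose, 13 and 1 over the list alone; 4.76e-09) and oocyte genes of -0.52 (29 of 30 fell, 30 over the list alone; 3.96e-13). Without OP50 replicate 2 only 10 oocyte genes fell, without OP50 replicate 1 only 5 molting genes and without L1 replicate 1 only 3 vitellogenins. With an estimated correlation the adjusted p of these 6 lists was 0.621, 0.677, 0.528, 0.210, 0.621 and 0.677.

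Lists not called by camera in any comparison of single groups numbered 17 of 46. They were C-type lectins, lysozymes, saposin-like and antimicrobial peptide genes, the intracellular pathogen response, cytochrome P450s, DAF-16 class I and class II genes, the endoplasmic reticulum unfolded protein response, and fasting-induced genes. The others were dauer and larval arrest genes, histones, intestine markers, male-enriched genes, the methionine cycle, the propionate shunt and the propionate pathway that needs vitamin B12. Camera tests for a shift in 1 direction against other genes, so these lists are not shown to be unchanged. On L1, 14 of 133 C-type lectins rose and 18 fell, and 13 of 70 cytochrome P450s rose and 7 fell. Other lists had fewer calls, such as 1 of 15 genes of the endoplasmic reticulum response. A form of fry for changes in either direction called 38 lists for L1, 37 for L2 and 31 for L2 vs L1. It does not compare genes with other genes. The counts do not show whether reads of near-identical relatives among the vitellogenins, the hsp-16 pairs, the collagens, the gst and the abu genes were assigned to the right member.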

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

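The tests of shared reads and moult timing for the cuticle genes had predictions and bounds written before their values were computed, after the main results were seen. The other tests in this part, that of OP50 replicate 1 included, were chosen with their bounds after seeing the results.

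The results below are those where the effect of L2 against OP50 differed from that of L1 against OP50, by a test of the difference itself, which is L2 vs L1 (camera for lists, edgeR quasi-likelihood for genes, Benjamini-Hochberg adjusted p under 0.05). The values are L2 minus L1 in log2. They were the same calls as in the comparison of the strains, where no list held with an estimated correlation (adjusted p = 0.926) and many gene calls ended without 1 library.

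Lists with a higher median on L2 were SKN-1 targets by 1.25, glutathione S-transferases by 0.82 and oocyte and eggshell genes by 0.80. Lists with a lower median were molting genes by -1.93, hypodermis markers by -1.82, cuticle collagens by -1.69, pharynx markers by -1.64 and the heat shock response by -1.396. Neuron markers differed by -0.59 and body wall muscle markers by -0.52.

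Genes higher on L2 than on L1 were gst-30 by 4.19, gst-4 by 3.45, gst-12 by 3.41, B0205.13 by 3.32 and gst-14 by 2.63. Next came col-135 by 1.76, nit-1 (in the lists of both HIF-1 and SKN-1 targets) by 1.48, the desaturase gene fat-7 by 1.12, cdr-4 by 1.07 and gcs-1 by 0.97. The yolk protein genes vit-5 and vit-2 differed by 0.95 and 0.87, the p38 targets K08D8.5 and C17H12.8 by 0.94 and 0.62, and the oocyte and eggshell genes oma-1, cpg-1 and perm-4 by 0.87, 0.80 and 0.70. Smaller differences were those of sod-3 by 0.93, gpd-1 by 0.74, cpr-6 by 0.58, cysl-2 by 0.53, hrg-2 by 0.48 and gpd-4 by 0.48. Among these, gcs-1, sod-3, gst-4, gst-12, gst-14, gst-30 and B0205.13 were called against OP50 on L2 and not on L1.

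Genes lower on L2 than on L1 were the collagen genes dpy-4 by -3.73, dpy-13 by -3.57, rol-6 by -3.36 and col-41 by -3.25, the elongase gene elo-4 by -2.70 and the molting gene mlt-10 by -1.501. The heat shock genes hsp-16.2 and hsp-16.41 differed by -1.89 and -1.78, phy-2 by -1.83 and ugt-57 by -1.27. Tissue genes lower on L2 were unc-86 by -1.04, myo-5 by -0.86 and myo-3 by -0.73. Of the genes that rose on L1, vha-5 differed by -0.99, nhr-57 by -0.85, pck-1 by -0.64 and hlh-30 by -0.51. For genes with few reads on L2, the ratio of counts per library size of L2 over L1 was 0.0649 for K02E11.10, 0.0596 for abu-7 and 0.0218 for Y48G8AL.12.

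Lower collagen and molting genes on L2 could come from OP50 replicate 1, which had more collagen RNA than OP50 replicate 2. Without it the medians in L2 vs OP50 were -1.198 for the collagens (camera adjusted p = 5.76e-14, 15 rose and 30 fell) and -1.69 for the molting genes (3.08e-21, 11 fell), so that library alone did not make the lower medians, although with all libraries both calls were lost with an estimated correlation (adjusted p = 0.410 and 0.370). Reads shared between near-identical collagens would leave the family's total unchanged, yet the lowest OP50 share of counts in collagens was 1.51 times the highest L2 share, just above the bound of 1.5. Worms collected at different times relative to a moult could differ in these genes too. The difference between the OP50 replicates correlated at 0.173 with the difference of L1 minus L2 across 165 collagen and molting genes (Spearman 0.162, permutation p = 0.0131, genes not independent), against 0.125 across all 15600 genes, which leaves this open.

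Lower oocyte genes and higher neuron and muscle markers on L1 could come from a smaller share of oocyte and embryo RNA per worm. This would raise somatic markers alike only if they had no RNA in oocytes and embryos. The medians of the neuron, muscle and intestine markers, of which the intestine list was not called, ranged over 0.65, from 0.52 to 1.17. Shuffled genes gave less (permutation p = 2.0e-05, 100000 shuffles of 55 genes, genes not independent). The markers thus did not rise alike. Their RNA in oocytes and embryos was not measured apart, so the test cannot decide on a smaller share of that RNA. A single library did not make the pattern, since the oocyte median nearest 0 with 1 library left out was -0.83. The choice among the scalings tried did not either, since over them the oocyte median nearest 0 was -0.87 and the lowest neuron median 1.10459. These scalings differed little, with a median of all genes from 0.06 with RLE to 0.17 with upper-quartile scaling. Each takes the bulk of genes as unchanged, so a shift that all of them miss is not excluded. Stage and diet were not separated in these samples.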

How the results depend on the processing

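Most counts of calls stayed within 1.5 times their value under RLE and upper-quartile scaling, a stricter filter, nuclear protein-coding genes only, DESeq2, and fits of only the groups compared, which were not run for the mean of both strains. The balance of higher and lower calls did not hold: with RLE scaling it turned to 3250 and 3523 for L1 (from 3600 and 3083), 653 and 661 for L2 (from 719 and 604), 2878 and 2706 for L2 vs L1 (from 2638 and 2824) and 1978 and 2410 for the mean (from 2205 and 1858). It also turned with DESeq2 and when some libraries were left out, so which direction had more calls of any size is left open. Without a filter L2 vs OP50 had 2880 calls instead of 1323, and the cause was not tested. Calls with an absolute log2 fold change of at least 1, fewer by construction, numbered 2473 for L1, 844 for L2, 1877 for L2 vs L1 and 1006 for the mean, and 278 were shared by both strains. Higher and lower calls of this size numbered 1946 and 527 for L1 and 332 and 512 for L2. They were 218 and 1659 for L2 vs L1 and 695 and 311 for the mean. How this split depends on the scaling was not tested.

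Leaving out each library gave 3799 to 6038 calls for L1 vs OP50, 278 to 1360 for L2 vs OP50, 691 to 6019 for L2 vs L1 and 1725 to 3216 for the mean, and 162 to 931 shared calls. Fewer libraries lower the power, and which library matters was not tested further. A lone library of a group is assumed to vary like the others. With the replicate number as a block, which pairs libraries that share only a number (correlations of their deviations of -0.0126 for OP50 and L1, -0.00393 for OP50 and L2 and 0.152 for L1 and L2), 6528, 1244, 5254 and 4020 genes were called (616 rose and 628 fell for L2, a turned balance), and opposite calls of the strains went from 109 to 202. With the block these lists were no longer called: glycolysis (camera adjusted p = 0.0711) and p38 targets (0.0696) for L1, desaturases and elongases (0.0537) for L2, and ribosomal proteins (0.0782) and p38 targets (0.0699) for the mean. Opposite calls ran from 20 to 184 with 1 library left out and were 217 with DESeq2, and the cause was not tested.

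Camera with an estimated correlation called 0 lists for L1, 1 for L2, 0 for L2 vs L1 and 1 for the mean, against 12, 26, 10 and 20. Some lists lost their call with an estimated correlation below the preset one, such as autophagy and lysosome genes on L1 (-0.0154). A larger correlation therefore does not account for every loss. With an estimated correlation camera tests on the 3 residual degrees of freedom, against about as many as genes tested with a preset one. This alone lowers the power, so a lost call by itself does not show that genes of a list move together. Differences between replicates show that those of some lists did. Higher in OP50 replicate 1 were 40 of 41 sperm genes, 77 of 80 ribosomal protein genes and all 15 heat shock genes. Other lists were split, such as cytochrome P450s with 37 of 70. Where genes move together by more than the preset correlation, the p-values of camera with it are too small. The rotation test fry called 7, 7, 1 and 6, and the cause was not tested. Leaving out 1 library gave 11 to 18, 22 to 28, 10 to 12 and 19 to 23.

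The direction of 2 lists reversed in camera. The median of the sperm genes in L2 vs OP50 ran from -1.33 without OP50 replicate 2 to 0.34 without OP50 replicate 1 (camera adjusted p = 0.747), the library with more sperm RNA than its replicate (median log2 difference of 1.52), and the cause was not tested further. That of ribosomal proteins in the mean of both strains ran from 0.0257 without OP50 replicate 2 to 0.438 without OP50 replicate 1. Both medians are above 0, and the direction reversed without OP50 replicate 2, where the mean was -0.00322 (camera adjusted p = 0.795). The cause was not tested.

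No direction reversed in the 147 results of named genes. Calls that ended numbered 3 with DESeq2, 1 with RLE, 3 with upper-quartile scaling, 2 of 134 with the stricter filter, 16 with only the groups compared, 9 with the replicate block, and 19 to 45 with 1 library left out. The calls of 33 named genes on L1, 21 on L2 and 10 in L2 vs L1 held in every setting. In the simulation for L1 vs OP50, at this depth and with 2 libraries per group, only 5.97% of the 1.5-fold changes were called. That simulation changed few genes and gave 93 calls, against 6683 in the data. Its Benjamini-Hochberg cutoff was therefore stricter, so this share does not carry over to the data. Genes called in the data for L1 vs OP50 had a median absolute log2 fold change of 0.86. How many 1.5-fold changes were missed in the data was not tested. The share of false calls in the data was not tested either. In the simulations it was above the rate that the adjusted p threshold is meant to hold.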

Other observations

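Gene Ontology terms were tested after seeing the results, as were the tests of the heme genes at the end of this part. Against 10976 tested genes with a term and over 1066 terms of 10 to 300 genes (hypergeometric test, Benjamini-Hochberg), genes that rose on L1 held 60 of 81 cilium genes (20.3 expected, adjusted p = 3.48e-18), 98 of 146 ion channel genes (36.6 expected, 6.86e-24) and 38 of 47 potassium ion transport genes (11.8 expected, 1.16e-13). Genes that fell on L1 held 78 of 99 DNA repair genes (20.3 expected, adjusted p = 7.39e-33), 52 of 59 DNA replication genes (12.1 expected, 2.26e-26), 34 of 36 proteasome genes (7.399 expected, 1.71e-19) and 41 of 49 kinetochore genes (10.1 expected, 4.16e-19). These are a few picked after seeing them, as 22.045% of the terms were called among genes that rose on L1 and 20.8% among those that fell. The test takes genes as independent, which they are not, so these p-values are too small.

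Terms called numbered 10 among genes that rose on L2, 27 among those that fell, 219 among genes higher on L2 than on L1 and 191 among those lower, of which a few picked after seeing them are given here. On L2, genes that rose held 23 of 54 genes of glutathione transferase activity (2.72 expected, hypergeometric adjusted p = 2.43e-13) and 26 of 120 neuropeptide signaling genes (6.05 expected, 6.43e-08). Genes that fell on L2 held 33 of 143 collagen trimer genes (4.63 expected, adjusted p = 1.83e-16), 15 of 43 serine endopeptidase inhibitors (1.39 expected, 4.69e-10) and 9 of 31 lipid transport genes (1.003 expected, 3.08e-05). Higher on L2 than on L1 were 49 of 59 DNA replication genes (10.6 expected, adjusted p = 4.98e-25) and 33 of 36 proteasome genes (6.48 expected, 1.15e-19). Lower on L2 than on L1 were 22 of 26 basement membrane genes (4.83 expected, adjusted p = 1.13e-10) and 22 of 28 genes of the ciliary transition zone (5.21 expected, 1.07e-09).

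The rise of the heme genes on both strains could follow from a food poor in heme, since worms cannot make heme and L. lactis does not make it either, and hrg-1, hrg-4 and hrg-7 are known to rise when heme is scarce. No heme level was measured here, so this was not tested. A single library did not make the rise, since the lowest median of the heme genes in either comparison with 1 library left out was 3.43. The choice among the scalings tried did not either, with a lowest median of 3.76. Nor did reads of overlapping genes for the 6 members without an overlapping protein-coding exon, which had a median of at least 2.68. The members hrg-3 and hrg-7 overlap such an exon and were left out, so overlapping reads were not tested for them. A test would be to feed L1 or L2 with added heme and measure hrg-7 and hrg-1.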
